A study of Mus musculus and Homo sapiens with 21 samples.

How the data were processed

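Gene expression was measured by RNA sequencing in 15 mouse libraries and 6 human libraries of lung cells. Per the labels, cells were taken by positive selection with magnetic microbeads against Pdgfra or Epcam, RNA was selected by its polyA tail, and libraries were made with the Nextera XT kit. The labels name each mouse library as a different mouse, and in the human part each library is a replicate of its group. As deposited by the authors, each table holds whole-number counts per gene symbol, with no normalization applied. The labels name Bowtie2, Cufflinks and DESeq and the builds mm10 and hg19 without versions, roles or order. The program that made the counts, its gene annotation and the strand of the libraries are not stated, so counts of overlapping or antisense genes, and of close paralogs, may be split in unknown ways.

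The mouse table holds 23478 genes, with total counts of 11576617 to 24598892 in the 9 Pdgfra+ libraries and 9512341 to 32503307 in the 6 Epcam+ libraries. The human table holds 25245 genes, with totals of 20340719 to 40110233, and 116 human genes of the sex chromosomes were removed before any test. CPM values are counts scaled to the library total. Where a group has 0 counts in each library, the fold change is given as a bound against 3 counts over the group. These floors cover counting error only, since the counts come from amplified reads without molecular identifiers. No library was left out. In the least different pair of replicates, the chi-square per degree of freedom was 16.3, so no library is a copy of another in its group. Libraries of different groups were not compared in this way.

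Groups came from the labels. Counts were fitted with the edgeR quasi-likelihood method (edgeR 4.0.16 in R 4.3.3) after filterByExpr and TMM normalization, with 1 fit for the 9 Pdgfra+ libraries, 1 for the 6 Epcam+ libraries and 1 for the human libraries. For the 12 libraries of aged mice in both fractions, 1 fit with a term per group served the interaction tests. Another, with additive terms for fraction and treatment, served the comparison of Pdgfra+ with Epcam+ libraries (8 residual degrees of freedom against 6). The tests are two-sided, genes were called at a Benjamini-Hochberg adjusted p of 0.05 within a comparison, and SE values are those of the log2 fold change. A fixed set of 39 gene lists of cell types, pathways and matrix genes was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with p adjusted over the lists of a comparison. Camera with an estimated correlation is given beside it, since 1 of 107 list calls in the 6 main comparisons holds with it: the macrophage and monocyte list in Epcam+ cells with RA. Responses of the fractions were compared by an interaction term. Correlations between comparisons that share libraries were set against 20 simulations of unchanged groups, and set differences between lists against 100000 permutations of list members.

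The groups, comparisons, lists and rules for naming genes were fixed before the data were examined. The named genes are the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, up to 4 called members of each list with the smallest p, and 12 genes fixed beforehand. With fewer than 5 called genes, the 6 genes with the smallest p were named. Ptprc, Scgb1a1, CD68 and the MTRNR2L genes, and Tcf21 and Col3a1 in the plot of fibroblast genes, were chosen after their values were seen. Gene positions come from the GENCODE annotation of GRCm38. No human annotation of hg19 was at hand, so human positions are not given.

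The alternatives were the size factors of DESeq2, no low-count filter, a filter of at least 5 CPM in at least 2 libraries, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, the replicate number as a block, a fold threshold, fits with only the 2 groups compared or with all 15 mouse libraries, fry in place of camera, and leaving out each library of the compared groups in turn. Where this left a group with 1 library, that library was taken to vary like the other groups. Library totals in place of TMM, and fits without the libraries labelled young or without the RA PNX libraries, were added after the data were seen. The pipeline was tested on simulated data with genes changed 2-fold, 4-fold and 8-fold. At 4-fold, edgeR recovered 64.2% of changed genes with 2 against 2 Pdgfra+ libraries, 58.2% with 2 against 2 Epcam+ libraries, 38.8% with 3 against 3 human libraries and 29.9% for the difference between fractions.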

Results

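The study measured gene expression by RNA sequencing in lung cells enriched with magnetic beads for Pdgfra or for Epcam. Pdgfra is the platelet-derived growth factor receptor alpha, carried by lung fibroblasts, and Epcam is a surface protein of epithelial cells. The mouse part has 15 libraries. In aged mice, each of the 2 cell fractions has 2 libraries after sham surgery, 2 after partial pneumonectomy (PNX, removal of part of the lung, after which the remaining lung can regrow) and 2 after PNX with retinoic acid (RA) pretreatment. A further 3 libraries are labelled Pdgfra+ cells of young mice after PNX. The human part has 6 libraries labelled Pdgfra+ lung cells, 3 from controls and 3 from people with idiopathic pulmonary fibrosis (IPF), a scarring disease of the lung. Total counts per library, to which CPM values are scaled, ran from 9512341 to 32503307 in the mouse libraries and from 20340719 to 40110233 in the human libraries.

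Pdgfra, which lies on chromosome 5 from 75152292 to 75198215 in the mouse annotation, separated the fractions in aged mice. It stood at 2981 ± 470.0 CPM (SD, n = 2) in sham Pdgfra+ libraries and at 8.30 ± 1.20 CPM (SD, n = 2) in sham Epcam+ libraries. In the aged Pdgfra+ libraries it stood at 333 ± 374 CPM (SD, n = 2) after PNX and at 2039 ± 306 CPM (SD, n = 2) after PNX with RA. The 3 libraries labelled young Pdgfra+ held 2.31 ± 0.526 CPM of Pdgfra (SD, n = 3), below the level in every Epcam+ library of sham or PNX mice. The same 3 libraries held 89369 ± 18408 CPM (SD, n = 3) of Sftpc, the surfactant protein made by alveolar type 2 cells, against 378 ± 174 CPM (SD, n = 2) in the aged sham Pdgfra+ libraries. Ptprc, the leukocyte antigen CD45, was at 546 ± 118 CPM (SD, n = 2) in aged sham Pdgfra+ libraries and at 1068 ± 10.9 CPM (SD, n = 2) in aged sham Epcam+ libraries. It was at 2.24 ± 1.93 CPM (SD, n = 3) in the libraries labelled young Pdgfra+ and at 2.64 ± 1.32 CPM (SD, n = 2) in the Epcam+ libraries of RA-treated PNX mice.

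**Figure D1:**
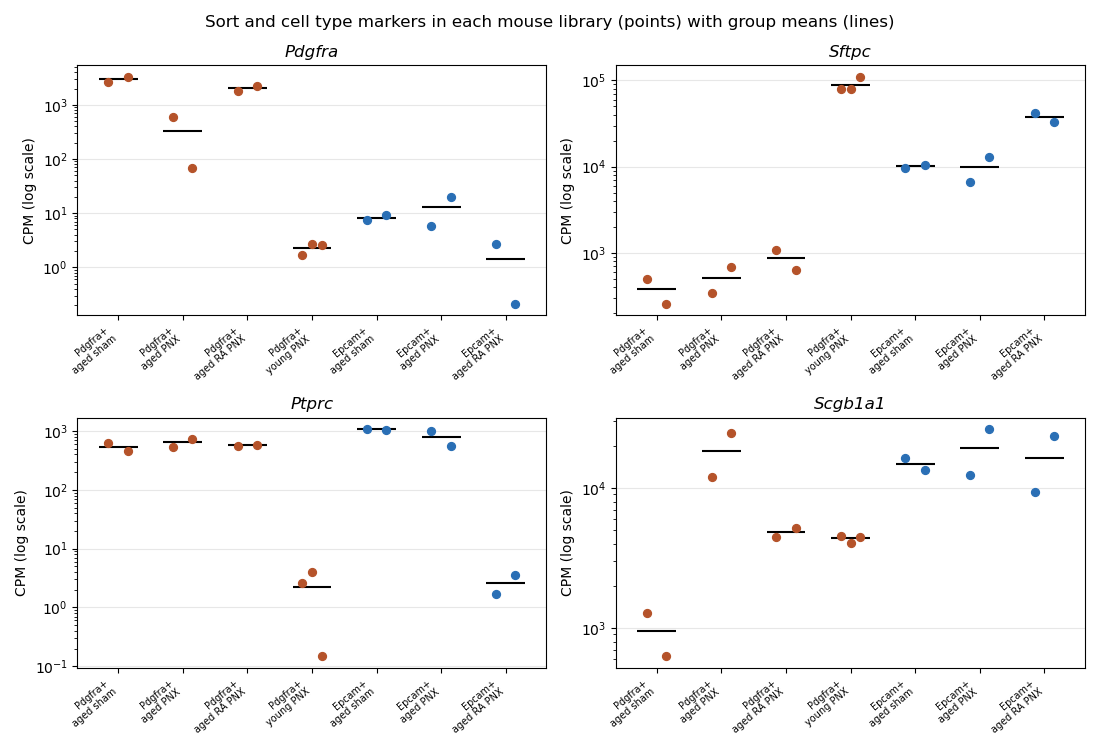
CPM (counts scaled to each library's total) on a log axis for Pdgfra, Sftpc, Ptprc and Scgb1a1 in each of the 15 mouse libraries (points) with group means (lines), by labelled group. The 3 libraries labelled young Pdgfra+ lie between 1.71 and 2.68 CPM for Pdgfra, and the aged PNX Pdgfra+ libraries lie at 68.8 and 598 CPM.

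Across the 12 libraries of aged mice, the Pdgfra+ fraction was richer in matrix genes and the Epcam+ fraction in alveolar epithelial genes. In Pdgfra+ against Epcam+ libraries, averaged over the 3 treatments, 16 of 23 tested genes for collagens and their processing were higher and 1 was lower (median log2 fold change 2.31, camera adjusted p = 9.02e-08, adjusted p = 0.194 with an estimated correlation). Of the elastic fibre genes, 13 of 17 were higher (median 2.95, camera adjusted p = 2.82e-09, adjusted p = 0.165 with an estimated correlation). Of the alveolar type 2 genes, 15 of 16 were lower (median -3.97, camera adjusted p = 1.73e-36, adjusted p = 0.0750 with an estimated correlation). Of 16746 genes tested with edgeR, 1863 were higher and 1921 lower. This fit took the difference between fractions as the same in each treatment, although the response to RA differed between them for 3774 genes. The total of 3784 fell to 2311 without the RA PNX libraries, to 2489 without aged RA PNX Pdgfra+ replicate 1 and to 2440 without aged sham Epcam+ replicate 2.

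The comparison of PNX with sham surgery in Pdgfra+ cells asked how the fibroblast fraction of an aged lung responds to loss of lung tissue. After PNX, genes that mark the fibroblasts lying beside the alveoli fell steeply: 11 of 15 tested lipofibroblast and alveolar fibroblast genes fell and 2 rose (median log2 fold change -4.29, camera adjusted p = 7.75e-12, adjusted p = 0.158 with an estimated correlation). Among them were Scube2, at -5.63 ± 0.47 (log2 fold change ± SE, as for each gene from here on), Slc7a10, a neutral amino acid carrier, at -5.61 ± 0.35, the matrix ligand Npnt at -4.63 ± 0.41 and Limch1 at -4.29 ± 0.26. Pdgfra fell by 3.17 ± 0.76 on the log2 scale (edgeR adjusted p = 0.0152), and Fgf10, a growth factor that mesenchyme sends to epithelium, fell by 3.22 ± 0.54 (edgeR adjusted p = 0.00307). Airway secretory genes rose, led in abundance by Scgb1a1, the secretoglobin of club cells, at 4.25 ± 0.48 (edgeR adjusted p = 0.000347), from 949.5 ± 458 CPM in sham to 18275 ± 8925 CPM after PNX (SD, n = 2 each).

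Members of other fibroblast and matrix lists fell as well. Of the elastic fibre genes, 8 of 17 fell and 0 rose by edgeR (median -1.04, camera adjusted p = 6.70e-05, adjusted p = 0.372 with an estimated correlation). Among them were Ltbp4 at -3.56 ± 0.40, Mfap4 at -3.27 ± 0.47, Fbln5 at -2.87 ± 0.24 and Eln, which encodes elastin, at -1.09 ± 0.30 (edgeR adjusted p = 0.0261). Of the genes for FGF ligands, receptors and feedback targets, 7 of 18 fell and 1 rose (median -0.45, camera adjusted p = 0.000539, adjusted p = 0.372 with an estimated correlation). Among them were Fgfr4 at -5.60 ± 0.54, Fgf7 at -3.64 ± 0.40 and Spry1 at -2.82 ± 0.28. Of the smooth muscle and myofibroblast genes, 5 of 15 fell (median -1.45, camera adjusted p = 0.000235, adjusted p = 0.372 with an estimated correlation). The myosin kinase gene Mylk led them at -4.42 ± 0.26. Of the adventitial fibroblast genes, which mark fibroblasts around vessels and airways, 2 of 14 fell, and the list was not called (median -0.50, camera adjusted p = 0.164). Of the collagen genes, 5 of 23 fell (median -0.69, camera adjusted p = 0.0354, adjusted p = 0.626 with an estimated correlation). Among them was Col6a3 at -1.96 ± 0.40. The collagen median was -0.02 without aged PNX replicate 2 (camera adjusted p = 0.937) and -0.43 without aged sham replicate 1 (camera adjusted p = 0.0619). The retinoid list, of retinoic acid targets and metabolism, was not called (median 0.34, camera adjusted p = 0.972), with 3 of its 19 genes higher and 3 lower, among the latter Lrat, which stores retinol as esters, at -3.13 ± 0.53.

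Genes of other cell types rose in the same libraries. Of the pan-epithelial genes, 10 of 15 rose (median 1.90, camera adjusted p = 1.16e-06, adjusted p = 0.372 with an estimated correlation). Among them were Krt18 at 2.60 ± 0.39 and Cdh1 at 2.07 ± 0.31. Of the club and goblet genes, 9 of 12 rose (median 2.71, camera adjusted p = 5.92e-06, adjusted p = 0.372 with an estimated correlation). Among them were Scgb3a2 at 3.86 ± 0.71 and Cyp2f2 at 3.17 ± 0.52. Of the macrophage and monocyte genes, 8 of 18 rose (median 1.24, camera adjusted p = 8.82e-06, adjusted p = 0.372 with an estimated correlation). Among them were Fcer1g at 2.55 ± 0.21 and Cd68 at 1.55 ± 0.24. Of the cell cycle genes, 26 of 42 rose and 1 fell (median 1.70, camera adjusted p = 5.28e-11, adjusted p = 0.372 with an estimated correlation). Among them were Ccna2 at 2.66 ± 0.40 and Aurkb at 2.77 ± 0.48. Mki67 stood at 2.82 ± 0.96 (edgeR adjusted p = 0.0588). Ribosomal protein genes rose in 31 of 41 cases (median 1.21, camera adjusted p = 4.46e-14, adjusted p = 0.372 with an estimated correlation). Among inflammatory genes, 11 of 21 rose and 1 fell (median 1.16, camera adjusted p = 0.000569, adjusted p = 0.372 with an estimated correlation). Among them were the iron-binding protein gene Lcn2 at 3.28 ± 0.30 and the neutrophil chemokine gene Cxcl5 at 3.23 ± 0.59. Immediate early and dissociation stress genes rose in 7 of 20 cases and fell in 2 (median 0.56, camera adjusted p = 0.00301, adjusted p = 0.372 with an estimated correlation), with Fosb at 3.43 ± 0.37, Fos at 2.36 ± 0.24 and Jun at 1.21 ± 0.23.

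In total, 3930 of 16463 genes were called after PNX, 2000 higher and 1930 lower. Each called gene named here lay higher, or lower, in each library of a group than in any library of the other group, which holds in the other comparisons as well. For the largest rises and falls this was a condition of naming. Of all 16463 tested genes, 11050 did not overlap between PNX and sham, and 9758 did not between RA and PNX. Among the genes that fell were Hoxd11 and Atp1a4, at 0 counts in both PNX libraries and at least 75.2-fold and 72.4-fold lower over the group, Colq, the collagen-like tail of acetylcholinesterase, at -8.29 ± 0.37 and Serpina3c at -7.02 ± 0.37. Among those that rose were Skint3, at least 77.8-fold higher over the group, Ms4a8a at 5.59 ± 0.49 and Reg3g, an antibacterial lectin of epithelium, at 5.16 ± 1.15. The count was 2205 without aged sham replicate 1, 1509 without aged sham replicate 2 and 2489 without aged PNX replicate 2. Without aged sham replicate 2, Pdgfra was at -2.97 (edgeR adjusted p = 0.0627) and Eln at -0.77 (edgeR adjusted p = 0.190). Eln was not called without aged PNX replicate 1 (-0.88, edgeR adjusted p = 0.129) or with library totals either (-1.07, edgeR adjusted p = 0.0534). Skint3 was not called without aged PNX replicate 2 (edgeR adjusted p = 0.0524) or by DESeq2 (adjusted p = 0.126).

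The comparison of RA pretreatment with PNX alone in Pdgfra+ cells of aged mice asked what RA changes in the fibroblast fraction. With RA, the alveolar fibroblast genes were higher again: 11 of 15 tested lipofibroblast and alveolar fibroblast genes rose and 2 fell (median log2 fold change 3.57, camera adjusted p = 4.17e-14, adjusted p = 0.0892 with an estimated correlation). Scube2 rose by 5.01 ± 0.46, Slc7a10 by 4.83 ± 0.34, Npnt by 4.35 ± 0.40 and Limch1 by 3.57 ± 0.25 on the log2 scale. Eln rose by 2.80 ± 0.32 (edgeR adjusted p = 0.000636), from 43.6 ± 10.7 CPM to 311 ± 7.17 CPM (SD, n = 2 each). Pdgfra stood 2.56 ± 0.74 higher on the log2 scale without passing the threshold (edgeR adjusted p = 0.0606).

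**Figure D2:**
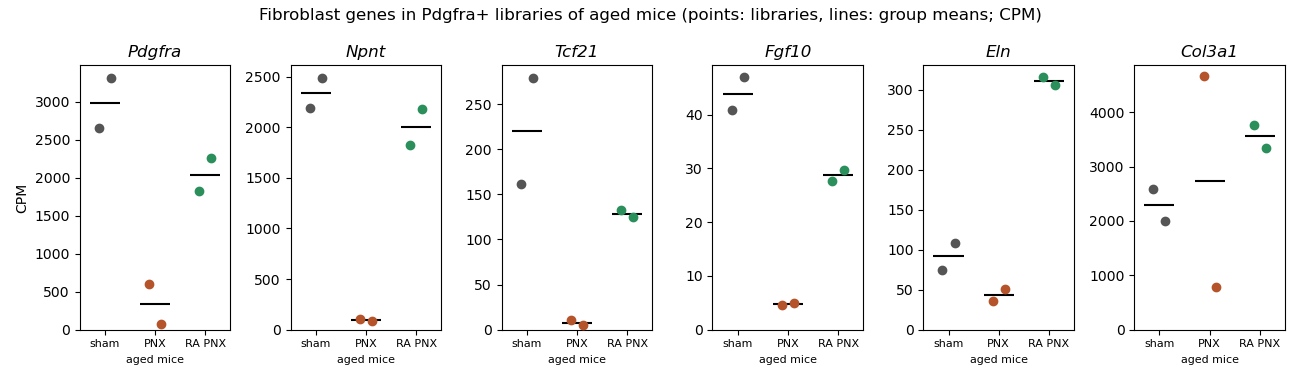
CPM on linear axes from 0 for 6 fibroblast genes in the Pdgfra+ libraries of aged mice after sham surgery, PNX, and PNX with RA (points, 2 per group) with group means (lines). Fgf10 had means of 43.9, 4.79 and 28.7 CPM in that order, and Eln had means of 91.5, 43.6 and 311 CPM.

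Some matrix and signalling genes rose with RA. Of the elastic fibre genes, 7 of 17 rose (median 1.22, camera adjusted p = 2.02e-08, adjusted p = 0.409 with an estimated correlation). Among them were the microfibril gene Mfap4 at 3.93 ± 0.48, Ltbp4 at 3.09 ± 0.39 and Fbln5 at 2.25 ± 0.24. Of the collagen genes, 4 of 23 rose (median 0.48, camera adjusted p = 0.00579, adjusted p = 0.635 with an estimated correlation). Without aged PNX replicate 2 the collagen median was -0.24 (camera adjusted p = 0.972). Of the basement membrane genes, 7 of 20 rose (median 1.02, camera adjusted p = 2.58e-08, adjusted p = 0.0892 with an estimated correlation). Among them was the laminin gene Lama2 at 3.07 ± 0.32. Of the FGF genes, 7 of 18 rose (median 0.75, camera adjusted p = 2.10e-05, adjusted p = 0.128 with an estimated correlation). Among them were Fgfr4 at 4.71 ± 0.52, Fgf7 at 2.92 ± 0.39, Spry1 at 2.49 ± 0.28 and Fgf10 at 2.55 ± 0.53 (edgeR adjusted p = 0.0161). Of the TGF-beta ligands and targets, 7 of 17 rose and 1 fell (median 0.91, camera adjusted p = 0.000271, adjusted p = 0.229 with an estimated correlation). Among them was Ctgf at 2.69 ± 0.42. Of the Wnt genes, 4 of 24 rose (median 0.47, camera adjusted p = 0.0481, adjusted p = 0.590 with an estimated correlation). Among them were the ligand Wnt2 at 3.60 ± 0.77 and the target Axin2 at 2.39 ± 0.42. The Wnt list was not called without aged PNX replicate 2 (median 0.24, camera adjusted p = 0.419), aged RA PNX replicate 1 (median 0.50, camera adjusted p = 0.0733) or aged RA PNX replicate 2 (median 0.48, camera adjusted p = 0.0600), nor with the replicate block (median 0.53, camera adjusted p = 0.0769) or library totals (median 0.52, camera adjusted p = 0.0528). Of the retinoid list, 2 of 19 rose and 1 fell (median -0.27, camera adjusted p = 0.602): the receptor gene Rarg rose by 1.12 ± 0.23, Rbp4 rose by 1.35 ± 0.32 and Dhrs3 stood at -1.23 ± 0.22. Rarb at -1.05 ± 0.38 (edgeR adjusted p = 0.119) and Cyp26b1 at -2.89 ± 1.06 (edgeR adjusted p = 0.125), both fixed beforehand, were not called. Of the 7 PDGF ligands and receptors, 0 were called over all genes by edgeR, and 2 were higher with p adjusted over the list alone (camera adjusted p = 0.469).

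Some genes of macrophages, neutrophils and ribosomes fell with RA, and 2 B cell genes rose. Of the macrophage and monocyte genes, 5 of 18 fell (median -0.63, camera adjusted p = 7.35e-05, adjusted p = 0.409 with an estimated correlation). Among them were Fcer1g at -1.84 ± 0.21 and Cd14 at -1.47 ± 0.28. Of the neutrophil genes, 3 of 8 fell (median -1.37, camera adjusted p = 0.00129, adjusted p = 0.409 with an estimated correlation). Among them was S100a9 at -2.90 ± 0.64. Of the lymphocyte genes, 2 of 16 rose (median 1.69, camera adjusted p = 0.00171, adjusted p = 0.466 with an estimated correlation), the B cell genes Cd79b at 2.42 ± 0.38 and Ms4a1 at 2.86 ± 0.63. Of the immediate early and dissociation stress genes, which cell handling can induce, 4 of 20 fell and 1 rose (median -0.54, camera adjusted p = 0.0108, adjusted p = 0.466 with an estimated correlation). Fosb stood at -3.02 ± 0.36 and Fos at -1.22 ± 0.23. That list was not called without aged PNX replicate 1 (median -0.27, camera adjusted p = 0.0862) or aged RA PNX replicate 1 (median -0.33, camera adjusted p = 0.109). Ribosomal protein genes fell in 22 of 41 cases (median -1.03, camera adjusted p = 2.96e-19, adjusted p = 0.409 with an estimated correlation). Interferon response genes rose in 4 of 21 cases (median 0.75, camera adjusted p = 0.000226, adjusted p = 0.466 with an estimated correlation). Among them was Mx1 at 3.90 ± 0.61. Scgb1a1 fell by 1.95 ± 0.43 on the log2 scale (edgeR adjusted p = 0.0217), and the club and goblet list was not called (median -0.50, camera adjusted p = 0.119). Xist, expressed from the inactive X chromosome of females, stood at -9.21 ± 2.06 (edgeR adjusted p = 0.0228). It was at 4715 and 11.3 CPM in the PNX libraries and at 3.35 and 4.89 CPM in the RA libraries, so these groups differed in the sex of their mice. Without aged PNX replicate 1 it stood at -1.48 (edgeR adjusted p = 0.0681), without aged RA PNX replicate 1 at -9.51 (edgeR adjusted p = 0.161) and without aged RA PNX replicate 2 at -8.96 (edgeR adjusted p = 0.206). With the replicate block it stood at -8.58 (edgeR adjusted p = 0.0677).

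In total, 1465 of 16463 genes were called with RA, 938 higher and 527 lower, among the former Colq at 7.33 ± 0.37 and Col13a1 at 5.73 ± 0.35 and among the latter Cxcl5 at -3.40 ± 0.60. Cxcl5 was not called without aged RA PNX replicate 1 (-3.23, edgeR adjusted p = 0.0831) or aged RA PNX replicate 2 (-3.59, edgeR adjusted p = 0.0795). The count was 908 without aged PNX replicate 2, 531 without aged RA PNX replicate 1, 394 without aged RA PNX replicate 2, 2239 without the libraries labelled young and 2378 with DESeq2. Fgf10 was not called without aged PNX replicate 1 (edgeR adjusted p = 0.0580), aged PNX replicate 2 (edgeR adjusted p = 0.0590), aged RA PNX replicate 1 (edgeR adjusted p = 0.0776) or aged RA PNX replicate 2 (edgeR adjusted p = 0.108).

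Of the genes lower after PNX, 882 were higher with RA, where independent lists would share 110.0, and of the genes higher after PNX, 498 were lower with RA, where independent lists would share 64.0. The number of genes called in the same direction in both comparisons was 0 among rises and 0 among falls by edgeR. Across genes, which are not independent replicates, the log2 fold changes of the comparisons had a correlation of -0.826, and 20 simulations of unchanged groups that share the same 2 PNX libraries gave -0.525. Their covariance was -1.31, against -0.214 in the simulations, a difference of -1.09. Part of this excess may come from the shared PNX libraries, which are too few to split.

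RA-treated PNX mice and sham mice were compared directly in the Pdgfra+ fraction. Lcn2 was the gene called higher, at 2.79 ± 0.29 (edgeR adjusted p = 0.0443). Eln stood at 1.71 ± 0.30 (edgeR adjusted p = 0.0766), Pdgfra at -0.60 ± 0.70 (edgeR adjusted p = 0.836) and Fgf10 at -0.67 ± 0.49 (edgeR adjusted p = 0.716). The sham libraries had Xist at 5257 and 5032 CPM and Ddx3y at 0 CPM, and the RA libraries had Xist at 4.89 and 3.35 CPM and Ddx3y at 81.8 and 108 CPM. Treatment and sex therefore cannot be separated in this comparison, although Xist itself, at -10.34 ± 2.15, was not called (edgeR adjusted p = 0.102). The lipofibroblast and alveolar fibroblast list was lower in the RA group (median -0.63, camera adjusted p = 0.00219, adjusted p = 0.333 with an estimated correlation), with 0 of 15 members called by edgeR. Club and goblet genes were higher (median 2.35, camera adjusted p = 2.57e-14, adjusted p = 0.206 with an estimated correlation), with 9 of 12 members passing with p adjusted over the list alone. Cell cycle genes were higher too (median 1.13, camera adjusted p = 1.39e-18, adjusted p = 0.346 with an estimated correlation), with 18 of 42 passing with p adjusted over the list alone. The edgeR count of 1 of 16463 genes, with 1697 at an unadjusted p under 0.05, was 437 with DESeq2, 52 with limma-voom, 663 with only these 2 groups in the fit and 0 with a stricter filter.

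The comparison of young with aged mice after PNX asked how the fibroblast fraction differs with age. The libraries labelled young Pdgfra+ carried an epithelial profile: 16 of 16 tested alveolar type 2 genes were higher than in the aged PNX Pdgfra+ libraries (median 6.01, camera adjusted p = 5.90e-21, adjusted p = 0.326 with an estimated correlation). Sftpc stood at 7.93 ± 0.70, the aspartic protease gene Napsa at 6.27 ± 0.41, the surfactant lipid enzyme gene Lpcat1 at 6.04 ± 0.31 and Ager, a marker of alveolar type 1 cells, at 5.30 ± 0.26. Pdgfra stood at -6.75 ± 0.77 (edgeR adjusted p = 5.68e-05) and Pdgfrb at -7.37 ± 0.59 (edgeR adjusted p = 5.03e-06). Of the macrophage and monocyte genes, 18 of 18 were lower (median -7.08, camera adjusted p = 2.80e-24, adjusted p = 0.238 with an estimated correlation). Among them were C1qb at -7.85 ± 0.30 and Fcer1g at -6.75 ± 0.22. The libraries labelled young held almost none of the gene used for the sort, so age and cell type cannot be separated in these differences.

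Matrix and fibroblast genes were lower in the libraries labelled young. Of the adventitial fibroblast genes, 12 of 14 were lower (median -3.96, camera adjusted p = 0.000176, adjusted p = 0.455 with an estimated correlation). Among them was Pi16 at -5.60 ± 0.36. Of the collagen genes, 15 of 23 were lower and 4 higher (median -3.71, camera adjusted p = 0.0133, adjusted p = 0.662 with an estimated correlation). Among them was Col6a3 at -5.58 ± 0.41. Of the elastic fibre genes, 13 of 17 were lower and 1 higher (median -3.04, camera adjusted p = 0.000176, adjusted p = 0.480 with an estimated correlation). Among them were Mfap4 at -5.76 ± 0.46 and Eln at -1.99 ± 0.28. Of the genes of cholesterol and fatty acid synthesis, 20 of 23 were higher and 1 lower (median 1.89, camera adjusted p = 3.94e-11, adjusted p = 0.455 with an estimated correlation). Among them were Scd1 at 6.29 ± 0.41 and Fasn at 4.95 ± 0.25. All 7 of 7 MHC class II genes were higher (median 2.27, camera adjusted p = 0.00322, adjusted p = 0.455 with an estimated correlation). Among them was Cd74 at 3.31 ± 0.48. In total 8279 of 16463 genes were called, 3799 higher and 4480 lower. With library totals in place of TMM the median of all genes was -0.49, and 2315 genes were higher and 6185 lower, which is 27.2% higher against 45.9%.

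Against the same libraries labelled young, the aged RA PNX Pdgfra+ libraries differed in 8840 of 16463 genes, 4918 higher and 3922 lower. With library totals the median of all genes was 0.60 and the split was 6823 higher and 2441 lower, which is 73.7% higher against 55.6%. Pdgfra stood at 9.31 ± 0.85 and Sftpc at -7.20 ± 0.68, and 13 of 15 lipofibroblast and alveolar fibroblast genes were higher and 1 lower (median 4.91, camera adjusted p = 1.25e-09, adjusted p = 0.184 with an estimated correlation). The change with RA was also set against the difference between young and aged libraries, which asks whether RA moves aged cells toward young ones. Across genes, the correlation of the log2 fold changes was 0.148 ± 0.191 (jackknife SE over libraries), while unchanged groups against the same 2 shared aged PNX libraries gave 0.575 in simulation. The covariance was 0.394 against 0.213 simulated, a difference of 0.181. Genes higher in both comparisons numbered 296 (216 for independent lists), genes lower in both 265 (143), genes higher with RA and lower in the young libraries 356 (255), and genes lower with RA and higher in the young libraries 105 (122). Part of any excess may come from the shared libraries. The correlation lay below its simulated value and the covariance above. The simulated groups differed only by the spread between libraries. Real differences in 1 comparison alone would thus lower the correlation below its simulated value, so it cannot be judged against that value. Since the libraries labelled young held almost no Pdgfra, these values cannot tell whether RA moves aged fibroblasts toward young ones.

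The comparison of PNX with sham surgery in Epcam+ cells asked how the epithelial fraction of the aged lung responds. Cell cycle genes were higher after PNX, with 25 of 42 passing with p adjusted over the list alone and 0 over all genes by edgeR (median 1.28, camera adjusted p = 1.39e-34, adjusted p = 0.238 with an estimated correlation). Mki67, carried by dividing cells, reached 603 ± 102 CPM (SD, n = 2) after PNX, with a log2 fold change of 1.69 ± 0.40 (edgeR adjusted p = 0.535). Mesothelial genes, of the lining of the lung surface, were higher in 9 of 9 cases with p adjusted over the list alone (median 1.31, camera adjusted p = 6.47e-17, adjusted p = 0.238 with an estimated correlation). Collagen genes passed in 10 of 23 cases with p adjusted over the list alone (median 0.93, camera adjusted p = 3.14e-13, adjusted p = 0.406 with an estimated correlation). Ciliated cell genes were lower in 7 of 13 cases with p adjusted over the list alone (median -1.03, camera adjusted p = 1.21e-14, adjusted p = 0.406 with an estimated correlation). These libraries also held the leukocyte gene Ptprc, at 1068 ± 10.9 CPM in sham and 781 ± 313 CPM after PNX (SD, n = 2 each). Epcam was at 135 ± 23.2 and 121 ± 46.8 CPM (SD, n = 2 each). The rises of cell cycle and collagen genes therefore cannot be assigned to epithelial cells.

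No gene of the alveolar type 1 and type 2 lists was called between these groups by edgeR. Sftpc stood at 0.02 ± 0.39 (edgeR adjusted p = 0.997), Ager at 0.60 ± 0.44 (edgeR adjusted p = 0.851), Pdgfa, the epithelial ligand of Pdgfra, at 0.03 ± 0.32 (edgeR adjusted p = 0.994) and Epcam at -0.12 ± 0.30 (edgeR adjusted p = 0.973). The alveolar type 2 list had a median of 0.38 with 0 of 16 members called by edgeR (camera adjusted p = 0.000253, adjusted p = 0.484 with an estimated correlation). The alveolar type 1 list had a median of 0.42 with 0 of 16 members called by edgeR (camera adjusted p = 0.0391, adjusted p = 0.818 with an estimated correlation). It was not called without aged sham replicate 1 (median -0.06, camera adjusted p = 0.351), aged PNX replicate 1 (median 0.51, camera adjusted p = 0.118) or aged PNX replicate 2 (median 0.31, camera adjusted p = 0.197), nor without the RA PNX libraries (median 0.44, camera adjusted p = 0.0902). The genes with the smallest p were Iqgap3 at 2.69 ± 0.35, Hmox1, which degrades heme, at 2.40 ± 0.30, the mesothelial gene Lrrn4 at 1.58 ± 0.24, the protease gene Pappa2 at 3.48 ± 0.53, the mitotic cyclin gene Ccnb1 at 1.98 ± 0.31 and Lrg1 at 1.64 ± 0.26 (edgeR adjusted p = 0.518 each). DESeq2 called all 6, with an adjusted p from 4.90e-09 (Hmox1 and Iqgap3) to 3.77e-05 (Lrg1). Over all 15673 genes tested edgeR called 0, with 1134 at an unadjusted p under 0.05, while DESeq2 called 141, limma-voom 0 and edgeR without a low-count filter 185. On data simulated for this comparison, edgeR recovered 58.2% of genes changed 4-fold and 5.97% of genes changed 2-fold.

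The comparison of RA pretreatment with PNX alone in Epcam+ cells asked what RA changes in the epithelial fraction. Alveolar epithelial genes rose: 15 of 16 alveolar type 1 genes (median log2 fold change 2.11, camera adjusted p = 2.58e-07, adjusted p = 0.656 with an estimated correlation) and 15 of 16 alveolar type 2 genes (median 1.82, camera adjusted p = 2.05e-08, adjusted p = 0.598 with an estimated correlation). Sftpc rose by 1.95 ± 0.40 on the log2 scale, from 9775 ± 4454 CPM to 37410 ± 6249 CPM (SD, n = 2 each), Ager by 2.61 ± 0.46, Emp2 by 2.40 ± 0.26 and the water channel gene Aqp5 by 2.11 ± 0.31. Ager was not called without aged PNX replicate 1 (2.25, edgeR adjusted p = 0.0502). Pdgfa rose by 1.84 ± 0.33 (edgeR adjusted p = 0.00573) and Pdgfb by 2.08 ± 0.31. Leukocyte genes fell furthest: 17 of 18 macrophage and monocyte genes fell (median -8.06, or -7.82 with members at 0 set to their bounds, camera adjusted p = 5.57e-46, adjusted p = 0.0218 with an estimated correlation).

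Among those macrophage genes, the lectin gene Chil3 stood at -9.06 ± 0.38 and Itgax at -7.96 ± 0.39, and C1qc was at least 374.69-fold lower over the group. The leukocyte receptor gene Pira6, which has close paralogs, was at least 1252.6-fold lower and the cytokine gene Il1b at least 521.76-fold lower. Of the lymphocyte genes, 12 of 16 fell (median -4.79, or -4.16 with members at 0 set to their bounds, camera adjusted p = 1.66e-07, adjusted p = 0.598 with an estimated correlation). Among them was the T cell receptor chain gene Cd3e, at least 210.4-fold lower. Of the neutrophil genes, 6 of 8 fell (median -5.40, or -4.06 with members at 0 set to their bounds, camera adjusted p = 0.00101, adjusted p = 0.656 with an estimated correlation). Of the endothelial genes, 8 of 16 fell and 1 rose (median -3.39 with members at 0 set to their bounds, camera adjusted p = 9.54e-05, adjusted p = 0.634 with an estimated correlation). Mesothelial genes fell in 9 of 9 cases (median -2.11, camera adjusted p = 3.87e-05, adjusted p = 0.598 with an estimated correlation).

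Proliferation genes and some airway genes fell as well. Of the club and goblet genes, 7 of 12 fell and 1 rose (median -1.75, camera adjusted p = 0.0257, adjusted p = 0.634 with an estimated correlation). Among them were Bpifa1 at -7.42 ± 0.50, Reg3g at -4.33 ± 0.57 and Cyp2f2 at -1.51 ± 0.24. Scgb1a1 overlapped between the groups, at 19338 ± 9908 CPM after PNX and 16436 ± 9928.5 CPM with RA (SD, n = 2 each). The ciliated list overlapped as well, with 0.287% and 0.156% of counts after PNX and 0.284% and 0.183% with RA. Of the cell cycle genes, 32 of 42 fell (median -2.28, camera adjusted p = 6.28e-12, adjusted p = 0.598 with an estimated correlation). Among them were Mcm3 at -3.94 ± 0.31, Rrm2 at -3.37 ± 0.29 and Mki67 at -2.27 ± 0.41. Ptprc went from 781 ± 313 CPM to 2.64 ± 1.32 CPM (SD, n = 2 each) in the same libraries. The fall of cell cycle genes therefore cannot be assigned to epithelial cells. Of the basement membrane genes, 11 of 19 rose and 4 fell (median 1.28, camera adjusted p = 0.00953, adjusted p = 0.656 with an estimated correlation). Among them was Npnt at 2.10 ± 0.28, and Eln fell by 2.70 ± 0.41. Of the retinoid list, 5 of 16 fell (median -0.68, camera adjusted p = 0.194), among them Aldh1a2, which makes retinoic acid, at -3.58 ± 0.37. In total 4664 of 15673 genes were called, 1905 higher and 2759 lower, and the count was 2761 without aged PNX replicate 1. The largest rises included genes of the vomeronasal receptor family, such as Vmn2r10 at 4.75 ± 0.91, whose reads cannot be assigned with certainty among near-identical copies. Pdgfra stood at -3.12 ± 0.91 (edgeR adjusted p = 0.0366) and was not called without aged PNX replicate 2 (-2.01, edgeR adjusted p = 0.194) or aged RA PNX replicate 2 (-2.29, edgeR adjusted p = 0.0888), nor with the replicate block (-3.02, edgeR adjusted p = 0.0575). The basement membrane list was not called without aged PNX replicate 1 (median 1.05, camera adjusted p = 0.0587) or aged RA PNX replicate 1 (median 0.86, camera adjusted p = 0.0591).

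Against sham, the Epcam+ libraries of RA-treated PNX mice differed in 5183 of 15673 genes, 2199 higher and 2984 lower. The alveolar type 1 list was higher (median 2.41, 14 of 16 members called, camera adjusted p = 1.71e-08, adjusted p = 0.689 with an estimated correlation), with Ager at 3.20 ± 0.47. The macrophage and monocyte list was lower (median -8.28, or -7.66 with members at 0 set to their bounds, 17 of 18 members called, camera adjusted p = 8.97e-42, adjusted p = 0.0252 with an estimated correlation). Pdgfa stood at 1.87 ± 0.33 (edgeR adjusted p = 0.00497). The count was 1904 without aged sham replicate 1 and 2395 without aged sham replicate 2.

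**Figure D3:**
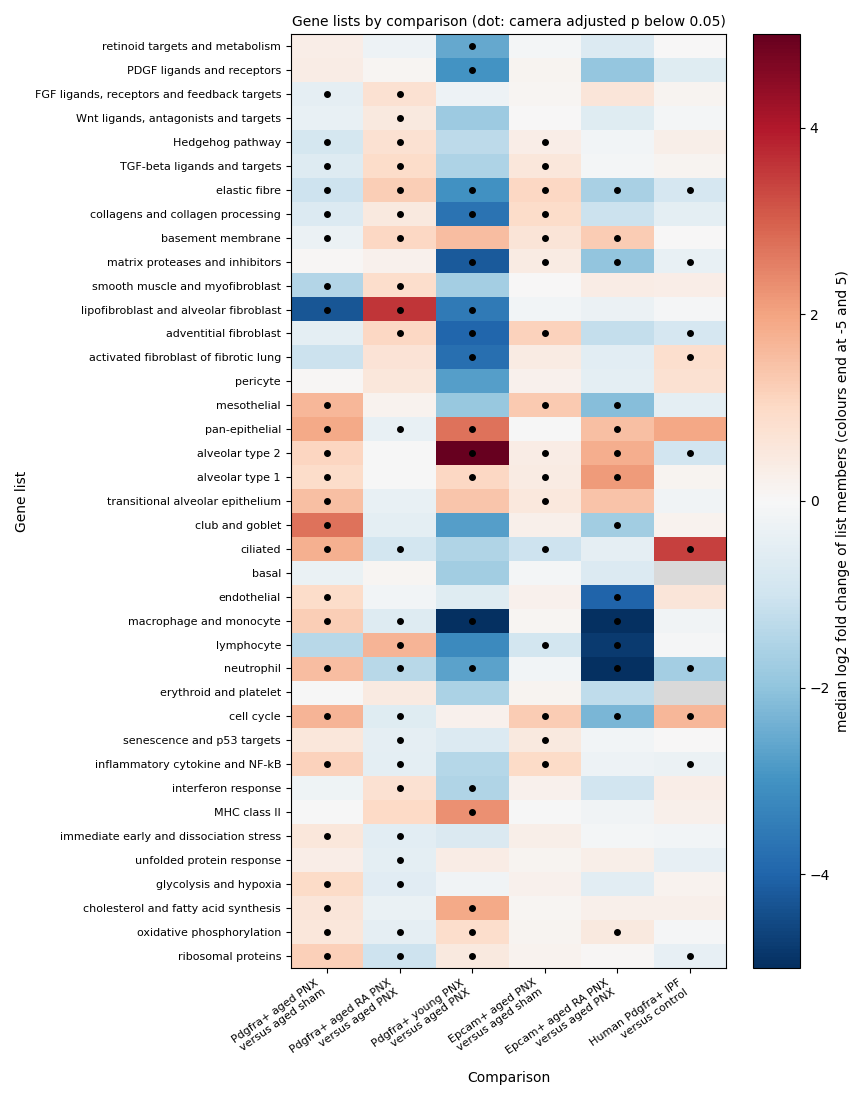
Median log2 fold change of the tested members of each of 39 gene lists (vertical axis) in the 6 main comparisons (horizontal axis), as colour, with a dot where camera with a preset correlation gave an adjusted p under 0.05 and grey for lists not tested. The lipofibroblast and alveolar fibroblast list has -4.29 after PNX and 3.57 with RA in Pdgfra+ cells, and the macrophage and monocyte list has -8.06 with RA in Epcam+ cells.

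The comparison of IPF with control asked what differs in the Pdgfra+ fraction of fibrotic human lung. Among the genes that rose in IPF were the metalloprotease genes MMP7 at 5.62 ± 0.94 (edgeR adjusted p = 0.0454), MMP12 at 4.14 ± 0.54 and MMP9 at 3.91 ± 0.53, the protease inhibitor gene TIMP3 at 4.07 ± 0.63, the BMP antagonist gene GREM1 at 5.31 ± 0.69, the secreted phosphoprotein gene SPP1 at 3.66 ± 0.55 and COL22A1 at 4.36 ± 0.65. The chemokine gene CCL22 rose by 5.41 ± 0.74, the phospholipase gene PLA2G2D by 8.31 ± 0.91, the actin-severing protein gene SCIN by 4.95 ± 0.60 and ALDH1A2, which makes retinoic acid, by 1.85 ± 0.31. Surfactant protein genes fell, SFTPA2 at -5.27 ± 0.62 and SFTPA1 at -5.21 ± 0.64, and reads of these near-identical paralogs cannot be assigned with certainty. MFGE8, whose product marks dying cells for uptake, stood at -4.75 ± 0.39. The receptor genes IL18R1, IL1R2 and FLT3 fell as well, at -5.87 ± 0.61, -4.75 ± 0.59 and -4.67 ± 0.53.

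These libraries held little PDGFRA, at 8.39 ± 7.01 CPM in control and 0.861 ± 0.460 CPM in IPF (SD, n = 3 each; -2.33 ± 0.71, edgeR adjusted p = 0.242), and much of the leukocyte gene PTPRC, at 716 ± 124 and 444 ± 306 CPM (SD, n = 3 each). CD68, a macrophage gene, was at 1059.8 ± 262 CPM in control and 863 ± 695 CPM in IPF (SD, n = 3 each). Humanin-like MTRNR2L genes, nuclear copies of a mitochondrial ribosomal RNA whose reads cannot be told from it with certainty, took 23.8 ± 3.90% of counts in control and 51.1 ± 24.5% in IPF (SD, n = 3 each). They took 62.2% and 68.2% in IPF replicates 2 and 3, but 23.0% in IPF replicate 1. CPM values are scaled to totals that include these counts, so those of other genes are lowered in IPF replicates 2 and 3. Cell cycle genes were higher in IPF, with 34 of 41 passing with p adjusted over the list alone and 0 over all genes by edgeR (median 1.67, camera adjusted p = 2.33e-34, adjusted p = 0.485 with an estimated correlation). Of the alveolar type 2 genes, 2 of 16 fell (median -0.98, camera adjusted p = 0.000230, adjusted p = 0.504 with an estimated correlation). Their median ran from -1.70 to -0.54 with 1 library left out, and the list was called in 6 of 6 fits. Of the genes of activated fibroblasts, 2 of 12 rose, GREM1 and SPP1 (median 0.85, camera adjusted p = 0.00244, adjusted p = 0.504 with an estimated correlation). The list lost its call in 2 of the 6 fits with 1 library left out, with a median from -0.02 to 1.08. COL1A1 was at 8.54 ± 7.97 CPM in control and 1.49 ± 1.60 CPM in IPF (SD, n = 3 each), so this rise cannot be assigned to fibroblasts. Of the adventitial fibroblast genes, 0 of 7 were called by edgeR and 2 were lower with p adjusted over the list alone (median -0.86, camera adjusted p = 0.00149, adjusted p = 0.485 with an estimated correlation). Of the elastic fibre genes, 0 of 11 were called by edgeR and 2 were lower with p adjusted over the list alone (median -0.86, camera adjusted p = 0.00335, adjusted p = 0.485 with an estimated correlation). With 1 library left out, the adventitial list was called in 6 of 6 fits (median -0.97 to -0.52) and the elastic fibre list in 5 of 6 (median -1.29 to -0.69). The collagen list was not called (median -0.49, camera adjusted p = 0.594). Of the matrix proteases and inhibitors, 3 of 16 rose, and the list was called upward although its median was -0.36 (camera adjusted p = 0.0216, adjusted p = 0.557 with an estimated correlation). With 1 library left out, it was called in 4 of 6 fits, with a median from -0.42 to 0.18 and a camera adjusted p up to 0.158. Of the macrophage and monocyte genes, 0 of 16 were called by edgeR (median -0.17, camera adjusted p = 0.567). Other lists of cell types were called, though not with an estimated correlation. With 1 library left out, the neutrophil list was called in 6 of 6 fits (median -2.01 to -1.33, camera adjusted p up to 0.0443). The ciliated list was called in 5 of 6 (median 0.54 to 4.68, camera adjusted p up to 0.168).

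In total 65 of 14758 human genes were called, 40 higher and 25 lower, and the count was 297 without a low-count filter, 544 with DESeq2 and 12 to 47 with 1 library left out. With library totals the median of all genes was -0.84, and 337 genes were called, 24.6% of them higher against 61.5%. AMPH, at -5.51 ± 0.42, and MFGE8 were called in each of the 6 fits with 1 library left out, while the largest rises were called in fewer. MMP7 and MMP12 were called in 1 of 6 fits, with edgeR adjusted p up to 0.173 and 0.0726. TIMP3, COL22A1 and CCL22 were called in 2 of 6, with edgeR adjusted p up to 0.198, 0.168 and 0.133, and GREM1 and SCIN in 3 of 6, with edgeR adjusted p up to 0.106 and 0.0569. PLA2G2D was called in 5 of 6, with edgeR adjusted p up to 0.0607. Among the falls, FLT3 was called in 5 of 6 and IL18R1, IL1R2, SFTPA1 and SFTPA2 in 4 of 6, with edgeR adjusted p up to 0.0560, 0.0689, 0.107, 0.105 and 0.0928.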

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

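The tests of technical explanations given here were chosen after the results were seen; the tests of a difference between the fractions were planned.

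The response to PNX differed between Epcam+ and Pdgfra+ cells of aged mice in a test of the difference itself. It was called for 1123 of 16746 genes, 774 with a higher log2 fold change in Epcam+ cells and 349 with a lower one. Eln differed by 2.43 ± 0.40 (edgeR adjusted p = 0.00494), as it was lower after PNX in both Pdgfra+ libraries and higher in both Epcam+ libraries. The lipofibroblast and alveolar fibroblast list differed by a median of 2.97 (camera adjusted p = 8.00e-09, adjusted p = 0.113 with an estimated correlation) and the ciliated list by -3.00 (camera adjusted p = 2.55e-11, adjusted p = 0.237 with an estimated correlation). The count was 484 without aged sham Pdgfra+ replicate 2, 673 without aged PNX Pdgfra+ replicate 2, 440 without aged sham Epcam+ replicate 1 and 498 without aged sham Epcam+ replicate 2.

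The response to RA differed between the fractions for 3774 of 16746 genes, 1384 higher and 2390 lower in Epcam+ cells. Eln differed by -5.42 ± 0.44 (edgeR adjusted p = 1.06e-05) and Pdgfra by -5.59 ± 1.37 (edgeR adjusted p = 0.0142). Ager differed by 2.97 ± 0.57 (edgeR adjusted p = 0.00386), Pdgfa by 1.91 ± 0.41 (edgeR adjusted p = 0.00729) and the retinoic acid receptor gene Rarb, called in neither fraction alone, by 1.36 ± 0.42 (edgeR adjusted p = 0.0400). The macrophage and monocyte list differed by a median of -7.57 (camera adjusted p = 9.32e-41, adjusted p = 0.00643 with an estimated correlation). The count was 2225 without aged RA PNX Pdgfra+ replicate 2, and sex is not separated from this difference: with RA, Ddx3y was at 81.8 and 108 CPM in Pdgfra+ and at 0 CPM in both Epcam+ libraries, Xist was at 4.89 and 3.35 CPM against 2575 and 3353 CPM, and both PNX groups mixed sexes.

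The libraries labelled young Pdgfra+ carried an alveolar type 2 profile with almost no Pdgfra. The tables argue against counts taken up by the alveolar type 2 genes as the cause: these 16 genes held at most 26.2% of a young library's counts, which would lower other genes by far less than the -6.75 of Pdgfra. Over 51 fibroblast and collagen genes, the young libraries differed from the Epcam+ libraries of RA-treated mice by a median of 0.104 in log2 CPM and from the aged sham Pdgfra+ libraries by -4.84, so epithelial cells in place of Pdgfra+ cells may be the source. Across genes, their mean rank correlation was 0.909 with the Epcam+ libraries of RA-treated mice and 0.598 with the aged sham Pdgfra+ libraries. Whether a label, the sort or the age of the mice lies behind this stays open and untested, since the series holds no other library of young mice.

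With RA, leukocyte genes were lower and alveolar epithelial genes higher in Epcam+ cells than after PNX alone. Of 42 tested members of the leukocyte lists 35 were called lower, by which fewer leukocytes and lower expression per leukocyte cannot be told apart, since both lower these genes. Fewer leukocytes as the whole cause would raise all epithelial genes alike, but the alveolar type 2 and the club and goblet medians differed by 3.58 (permutation p = 7.00e-05). The values argue against lower depth as well. A 1.75-fold step in depth within PNX went with a median fall of 0.156 in log2 CPM for leukocyte genes. For alveolar type 1 and type 2 genes it went with a median rise of 0.258, while a 1.77-fold step to RA went with 5.70 and 1.69. Each step compares 1 library with 1 other, and the 2 PNX libraries also differed in sex (Xist at 16.9 and 3909 CPM), so depth is not excluded. A purer sort of alveolar epithelium in the RA libraries and an effect of RA itself both stay open, and no batch is given in the labels. The Epcam+ RA libraries had a mean rank correlation of 0.769 with Epcam+ PNX libraries, while Epcam+ PNX and sham libraries had 0.958. With the libraries labelled young Pdgfra+, which are not labelled RA, it was 0.909. Low Ptprc was shared by those libraries too (2.24 against 2.64 CPM), so this profile was not particular to RA.

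In Pdgfra+ cells of aged mice, lipofibroblast and alveolar fibroblast genes were lower after PNX and higher again with RA. A lower share of all fibroblasts after PNX would lower each kind of fibroblast gene alike only if other cells held none of them. The median of this list lay below that of the adventitial list by -3.78 (permutation p = 0.00793, with genes taken as independent). But the adventitial gene Dcn was at 240 and 491 CPM in Epcam+ PNX libraries, where Pdgfra was at 5.88 and 19.6 CPM. In Pdgfra+ PNX libraries Dcn was at 1403 and 413 CPM, so the test cannot exclude a lower share. The rise with RA was not set against the adventitial list, whose called genes with the smallest p, Dpt, Clec3b, Mfap5 and Pi16, also rose. A single PNX library is excluded as the cause: with aged PNX replicate 1 or replicate 2 left out, the list median was -4.29 at its highest and -4.84 at its lowest. Sex is excluded, since the sham mice expressed Xist, the RA mice expressed Ddx3y, and both groups lay above PNX, by at least 3.57 in the list median. A loss of alveolar fibroblasts, a change in their expression, a sort that caught fewer of them after PNX and stress during cell handling all stay open: the immediate early and dissociation stress list had a median of 0.56 after PNX and -0.54 with RA, and the PNX libraries had a mean rank correlation of 0.923 with Epcam+ PNX libraries against 0.857 with Pdgfra+ sham libraries.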

How the results depend on the processing

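The fits with library totals, without the libraries labelled young and without the RA PNX libraries were chosen after the data were seen. Of 108 named genes, 107 kept direction and side of the threshold with the size factors of DESeq2, 100 with the DESeq2 Wald test, 106 with library totals and 101 with the replicate block. Of 107 list calls, 1 held with an estimated correlation, 57 with fry, 101 with library totals and 99 with the replicate block. With each library left out in turn, 411 of 490 gene results and 408 of 466 list results held.

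Counts of genes moved more, and the cause was not tested unless the setting itself uses fewer libraries or genes. With DESeq2 the count was 2378 for RA against PNX in Pdgfra+ cells (2239 in edgeR without the young libraries), 141 for PNX against sham in Epcam+ cells, 437 for RA against sham in Pdgfra+ cells, 544 in human cells and 2152 for the difference of the PNX effect. Without a low-count filter it was 185 for PNX in Epcam+ cells, 176 for RA against sham in Pdgfra+ cells and 297 in human cells. For RA against sham in Pdgfra+ cells it was also 52 with limma-voom, 663 with only the 2 groups in the fit, 65 with all 15 mouse libraries, 3 without the young libraries, and 0 with DESeq2 size factors, with a stricter low-count filter and with the replicate block. With all 15 mouse libraries in the fit, PNX in Epcam+ cells gave 1. Human cells gave 337 with library totals only and 39 with the replicate block, and MMP7 had an adjusted p of 0.0504 with DESeq2 size factors in edgeR and 0.127 with the block, where COL22A1 had 0.0523. Pdgfra+ against Epcam+ cells gave 2311 without the RA PNX libraries.

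With 1 library left out, the counts ran from 1509 to 3116 for PNX and from 394 to 1302 for RA in Pdgfra+ cells, from 0 to 1 for PNX and from 2761 to 5359 for RA in Epcam+ cells, and from 12 to 47 in human cells. They were 0 in each fit for RA against sham in Pdgfra+ cells and ran from 1904 to 5908 in Epcam+ cells, from 2440 to 4052 between the fractions, and from 440 to 1510 and from 2225 to 4527 for the differences of the PNX and RA effects. The correlation of the RA change with the young difference ran from 0.100 to 0.336. The collagen median had its lowest value of -1.80 after PNX without aged PNX Pdgfra+ replicate 1 and its highest of -0.0239 without replicate 2, where the test changed direction, and with RA it was 2.03 without replicate 1 and -0.24 without replicate 2. The alveolar type 1 median for PNX in Epcam+ cells ran from -0.0638 without aged sham replicate 1 to 1.13 without aged sham replicate 2.

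Residuals of libraries with the same replicate number had a mean correlation of -0.0555 in Pdgfra+, 0.00408 in Epcam+ and -0.0691 in human fits. In a group of 2 libraries the residuals mirror each other, so these values can show little about pairing. Pairing of Pdgfra+ with Epcam+ libraries was not checked by correlation. After PNX, Ddx3y was at 0 and 81.2 CPM in Pdgfra+ replicates 1 and 2, and at 58.9 and 0 CPM in Epcam+ replicates 1 and 2. With RA it was at 81.8 and 108 CPM in Pdgfra+ libraries and at 0 CPM in both Epcam+ libraries. PNX and RA libraries with the same number in the 2 fractions thus came from different mice. Ddx3y was at 0 CPM in the sham libraries of both fractions, so it cannot show this for them. With 2 or 3 libraries per group, changes of 2-fold were mostly out of reach, as edgeR recovered 11.9% of them in simulated Pdgfra+ data and 1.49% in simulated human data.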

Other observations

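The test of other splits of the human libraries was planned, and the other values were looked at after the results were seen.

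Genes called between human IPF and control libraries numbered 65, and the highest count among other splits of the 6 libraries into 3 and 3 was 0. The 10 splits are too few for a share under 0.05, and 1 of them, the real one, reached 65.

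Sex-linked genes differed among the mice of a group. In aged Pdgfra+ libraries, Ddx3y, on the Y chromosome, was at 0 CPM in both sham libraries, at 0 and 81.2 CPM after PNX and at 81.8 and 108 CPM after PNX with RA. In aged Epcam+ libraries it was at 0 CPM in both sham and both RA PNX libraries and at 58.9 and 0 CPM after PNX, where Xist was at 16.9 and 3909 CPM, so the PNX groups of both fractions mixed sexes.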
